A study of Mus musculus with 4 samples.

How the data were processed

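The series measured gene expression in the colonic mucosa of C57BL/6J mice with dual-colour Agilent whole mouse genome arrays. Each of the 4 samples set the RNA of mice kept for 4 weeks with Nod2-deficient mice (co-housed) directly against the RNA of control C57BL/6J mice, and each of these 4 pairs was hybridised on 2 arrays with the dyes swapped, 8 arrays in all. Per the labels' protocols, animals were adult and specific pathogen-free, RNA was purified on columns with DNase digestion, and 350 ng of total RNA was amplified from the poly(A) end and labelled with Cy3 or Cy5.

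Per the file headers, each array was scanned on an Innopsys instrument and quantified with Mapix 4.6.1, and the deposited values are the mean intensity of each spot and the median intensity of its local background at both wavelengths, not normalised. The deposited files also give, per the file headers, the percent of saturated pixels of each spot and a score that is 0 for a spot the software found and negative for a spot it did not find. A deposited table holds 1 log2 ratio per probe and sample. The authors do not state its scale, centring or direction, and per the submitters' processing notes limma was used, with its version and settings not given in the sources used here. Set against the present values, the columns of that table correlated with the mean of the dye-swapped arrays at r from 0.92 to 0.94 across probes, with slopes from 1.25 to 1.28 and medians of -0.010, -0.0054, -0.0067 and -0.0041, and they are read as centred log2 ratios, positive for higher in co-housed mice, on a scale somewhat wider than the present one.

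The labels list both dyes for both RNAs of every sample without saying which array is which. The dye of the co-housed RNA was taken from the deposited array names, so the direction of every ratio is likely rather than stated. The basis is the array names alone, and if they were wrong all directions would turn together. The direction of the deposited table was read against ratios turned by those names and is no second basis. Titles and source names number all 4 co-housed RNAs as replicate 1 and the control RNAs 1 to 4, while the descriptions number both 1 to 4, and the latter numbering was used. The 2 slides held 4 arrays each, with pairs 1 and 2 on slide 1 and pairs 3 and 4 on slide 2.

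Intensities were analysed in R 4.3.3 with limma 3.58.1, statmod 1.5.0 and version 1.17.8 of the data.table package. The plots were drawn in Python 3.11.15 with matplotlib 3.10.9. Background was corrected by normexp with an offset of 50, and log ratios were normalised within each array by loess with control spots at weight 0. Control spots were then left out, ratios were turned to co-housed over control, repeated spots of a probe were averaged, and the 2 dye-swapped arrays of a pair were averaged to 1 value. Averaging both dye orientations cancels a constant dye effect of a gene. Dye effects were sizeable. Over all tested genes, arrays of different pairs with the same dye correlated at a median r of 0.57. The 2 dye-swapped arrays of one pair did so at 0.29. The SD over dye-averaged pairs does not hold this spread. Averaging does not cancel cross-hybridisation, and normexp with an offset pulls the ratios of dim probes towards 0, so folds of weakly expressed genes are understated.

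A spot counted as detected when the software had found it and its mean intensity over background exceeded the median of the array's 153 negative control spots by 2.6 scaled median absolute deviations in that channel. This definition replaced a detection flag and processed signals of another scanner software that the planned analysis had assumed. These thresholds lay between 53.2 and 91.9 intensity units. Probes detected on at least 4 of the 8 arrays in either RNA were kept, 17597 of 41174. Of all probes, 32664 took 1 gene symbol from the platform annotation, 798 through their transcript accession and 1314 from the symbol in the files. A further 45 matched several genes and 6353 had no symbol, and these 6353 were tested under their identifiers where they passed the detection filter. For genes with several kept probes the probe with the highest mean intensity stood for the gene, which left 12586 genes and transcripts, 11762 of them with a gene symbol. A gene not detected on any array in one RNA is given as a bound, "at least N-fold": the mean of the detected RNA over the mean of the higher of the lowest detected signal and the gene's own signal on each array of the other RNA, from normalised channel values.

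The mean log2 ratio of the 4 pairs was tested against 0 with limma (lmFit and eBayes), and p-values were adjusted by the Benjamini-Hochberg method, with a threshold of 0.05. The SD given beside a ratio is that of the 4 pairs, n = 4. The hybridised pair was the unit. Each RNA's deviations from its group mean correlated with those of the RNA it shared arrays with at r of 0.69, 0.71, 0.39 and 0.57 across genes. Control RNA 3 correlated more with co-housed RNA 4 (r = 0.50) than with its own partner. That pairing comes from the shared arrays and does not show that the mice were related. The labels' design text gives 4 biological replicates. No label says that the RNAs are those of single animals, so p-values measure only the spread between these pairs.

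Whether the 4 pairs differed from one another was checked gene by gene with an F test of the pairs against the dye-swapped arrays within pairs, after removing the mean dye effect. Over 12586 genes 5.05% had p under 0.05, 5% being the share without any difference. No gene passed adjustment in that F test, with a smallest adjusted p of 0.82, and limma's moderated version gave 0 genes, 5.51% under 0.05 and a smallest adjusted p of 0.894. On simulated data, a between-sample SD of 0.1 on the log2 scale raised that share to 16.8% and one of 0.2 to 35.8%, against 5.2% with none. The pairs therefore differed by no more than repeated arrays of one pair. Although the labels give 4 biological replicates, the pairs are treated as 4 repeated measurements of one comparison, whose p-values describe technical spread.

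A total of 56 gene lists, pathways and cell type markers, were fixed before the data were examined. So were the test, the filter's rule of at least 4 of 8 arrays and the named-gene rule. All alternatives were too, except those said to be chosen after seeing the data. The definition of a detected spot was not fixed beforehand, since the files lacked the planned flag. The 50 lists with at least 5 tested genes were compared with all other genes by limma's camera, two-sided, with a preset correlation of 0.01 between genes and Benjamini-Hochberg adjustment over lists. Camera with an estimated correlation and fry served as alternatives. Fry asks whether the genes of a list differ from 0, not from the other genes, so its calls answer a different question. For each list the members that rose or fell were counted over all genes tested and also adjusted over the list alone. The named genes are the 12 with the highest and the 12 with the lowest log2 ratio among those past the threshold with 1 sign in all 4 pairs, up to 4 members with the smallest p of each list that passed and of 6 immune and defence lists in any case, and Nod2 and Nnt. Genes named outside this rule are said to have been chosen after their values were seen.

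Gene length was taken as the genomic span from first to last base in a RefSeq gene table of assembly GRCm38.p6, a proxy for transcript length, available for 93.5% of the tested genes and transcripts. The trend of the log2 ratio with the logarithm of that span was removed by loess as an alternative chosen after seeing the data.

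The limma and camera tests were tried on simulated log2 ratios of all 12586 genes, with independent noise at the spread of these arrays. Background correction, loess, the detection filter and the choice of probe were not run on simulated data. No spread between samples was added for the figures that follow. The limma test recovered 31.3% of 67 genes changed by 0.25 on the log2 scale, 92.5% of 67 changed by 0.5 and 100% of 66 changed by 1. Of its 151 calls, 1.32% were genes that had not been changed. On lists of 25 genes that vary independently, camera with the preset correlation called 4 of 4 shifted by 0.15 and 0 of 16 others. Alternatives covered background correction, normalisation, the detection filter, the choice of probe, the dye, the slide, the pairing, the variance prior, array weights, the deposited log2 table, the threshold and leaving out each pair. The processed signals of another scanner software, planned as an alternative, were not run because these files hold no such columns. In their place the scanner's background-subtracted median intensities, centred without loess, were chosen after seeing the data, as was leaving out array 6 (pair 3, co-housed RNA in Cy3), whose ratios correlated least with those of the other arrays. The number of arrays limits the precision throughout.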

Results

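The data set compares the colonic mucosa of C57BL/6J mice that lived for 4 weeks with Nod2-deficient mice with that of control C57BL/6J mice. Nod2 is a cytosolic sensor of bacterial peptidoglycan, and the title of the series concerns a gut microbiota that passes from the deficient animals to wild-type cage mates. The comparison therefore asks which colonic transcripts differ in wild-type mice that shared a cage with the mutants. There were 4 pairs of a co-housed and a control RNA, biological replicates per the labels, each measured on 2 dye-swapped arrays. Between 40.5% and 45.2% of the gene spots were detected per array and RNA, the median spot intensity over background lay between 31.3 and 58.1 units, and 12586 genes and transcripts were tested. Ratios are co-housed over control on the log2 scale, as mean ± SD over 4 pairs (n = 4). Their direction is likely, from the array names alone, since the labels do not assign the dyes. The 4 pairs differed by no more than repeated arrays of one pair (5.05% of genes with p under 0.05 in an F test between pairs), so the tests compare these RNAs and hold no evidence on the spread between mice.

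In co-housed mice, transcripts of blood vessel, connective tissue, macrophage and complement genes were higher and those of mucus-producing and absorptive epithelium were lower. These group calls hold in camera with a preset correlation between genes. With an estimated one camera called 0 lists (10 at an unadjusted p under 0.05, and 35 called by fry). A larger correlation does not account for that loss in every list, as given below. The highest ratios were those of Inmt, a methyltransferase of small amines, at 1.31 ± 0.20 (2.49-fold), of the secreted peptidase inhibitor Pi16 at 1.09 ± 0.18 and of Sertad3 at 1.03 ± 0.13. The lowest ratio was that of Sgk1, a kinase induced by corticosteroids that promotes sodium uptake, at -1.38 ± 0.12 (2.61-fold lower). It was followed by those of the hypoxia-induced gene Ankrd37 at -1.19 ± 0.11 and of Ly6m at -1.04 ± 0.05. Adjusted p-values of these 6 genes in limma lay between 0.000101 and 0.000395, and each had 1 sign in all 4 pairs. Of the 12586 genes and transcripts, 3485 (27.7%) passed the threshold, 1798 higher and 1687 lower (1119 and 3220 when arrays were centred on their median in place of loess), and 3454 of them had 1 sign in all 4 pairs.

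Most of these differences were small. The median absolute log2 ratio of the 3485 was 0.23, against a median SD over pairs of 0.098 across all genes, and 66 genes were higher and 26 lower by at least 1.5-fold. By the probe that stood for each gene, Inmt, Pi16 and Sertad3 were the 3 transcripts at least 2-fold higher, and Sgk1, Ankrd37, Ly6m and a transcript without a gene symbol were the 4 at least 2-fold lower. A second probe of Ifi27l2a stood at 1.22, against 0.59 for the probe used. Next among the higher genes came the matrix-associated growth regulator Ccn2 (0.99 ± 0.09), the endothelial tight junction gene Cldn5 (0.98 ± 0.02), the central complement component C3 (0.96 ± 0.01), Retnla, a product of alternatively activated macrophages (0.94 ± 0.17), and the immediate early transcription factor Egr1 (0.92 ± 0.14). They were followed by Csrp1 (0.91 ± 0.16), the macrophage lectin Clec10a (0.88 ± 0.07), the lysophospholipase Enpp2 (0.87 ± 0.05) and the coagulation factor gene F13a1 (0.86 ± 0.06). Next among the lower genes came the mitotic kinesin Kifc1 (-0.97 ± 0.21) with its near-identical copy Kifc5b (-0.73 ± 0.16), which these probes may not tell apart, Fam98b (-0.79 ± 0.20), the stress-induced mTOR inhibitor Ddit4 (-0.71 ± 0.19) and the giant cadherin Fat1 (-0.71 ± 0.12). Gbf1 (-0.70 ± 0.31), Baz1a (-0.68 ± 0.12), the goblet cell gene Rep15 (-0.68 ± 0.09) and the cytolinker Plec (-0.67 ± 0.28) completed them. The other probe of Fam98b stood at 0.00, that of Fat1 at -0.11, the weakest of 3 Baz1a probes at -0.18, the other Gbf1 probe at -0.32 and the weakest of 3 Plec probes at -0.33.

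**Figure D1:**
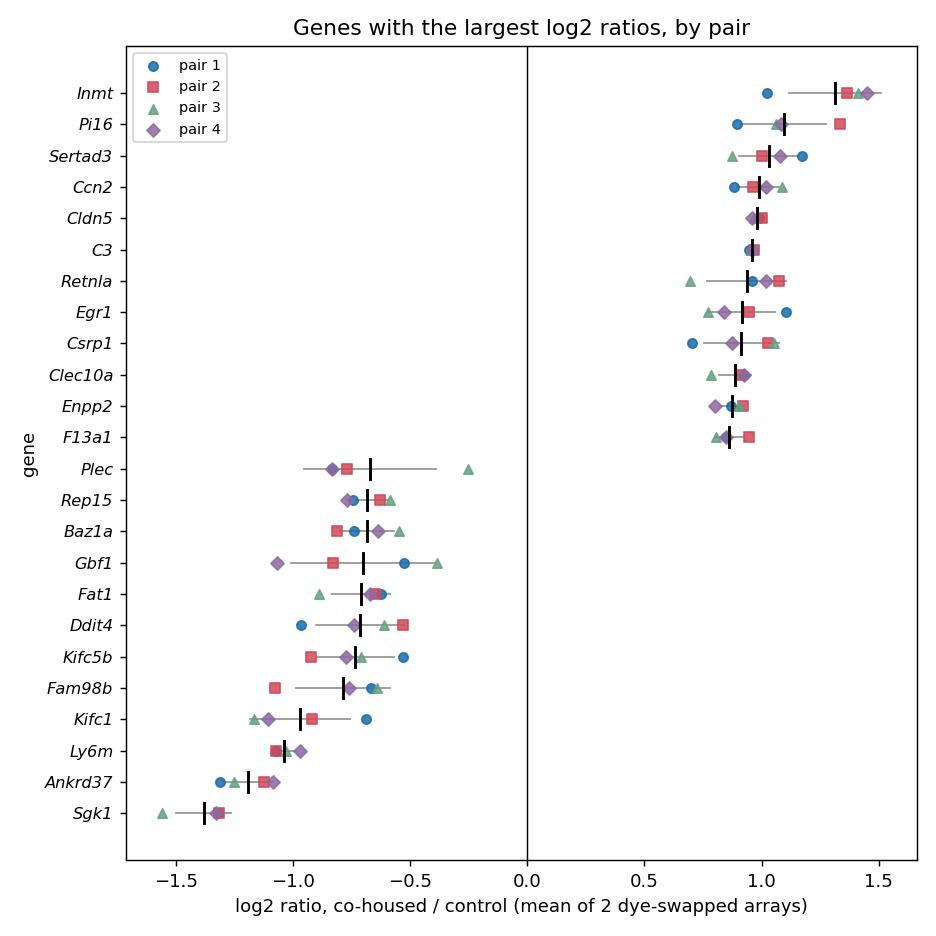
Log2 ratios (co-housed over control, horizontal axis) of the 12 highest and the 12 lowest genes past the threshold, with 1 point per pair (mean of 2 dye-swapped arrays), a vertical bar at the mean and a grey line of 1 SD to each side (n = 4). Points of each gene lie on one side of 0, from Inmt at 1.31 to Sgk1 at -1.38, and pair 3 of Plec at -0.25 lies apart from its other pairs.

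The count of genes depended on which arrays were used and on the pairing. It was 3063 with the slide as a block, 883 on slide 1 alone and 636 on slide 2 alone, 2025 when the co-housed and control RNAs were compared without pairing, and 2128, 1934, 3040 and 2106 without pair 1, 2, 3 or 4.

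Markers of several, though not all, non-epithelial cell types of the gut wall were higher as groups. Among 23 tested markers of macrophages and dendritic cells 17 rose and 0 fell (17 and 0 adjusted over the list alone), with a median log2 ratio of 0.33. They included Clec10a, the lysozyme Lyz2 (0.71 ± 0.11, its other probe at 0.34), the complement subunit gene C1qa (0.41 ± 0.03) and the antibody receptor Fcgr3 (0.45 ± 0.06, its other probe at 0.27). Camera gave an adjusted p = 4.59e-08, against an adjusted p = 0.170 with an estimated correlation. Complement and coagulation genes had the highest list median, 0.41, and 16 of 21 rose while 0 fell (17 and 0 adjusted over the list alone). Besides C3 and F13a1 these included complement factor D (Cfd, 0.86 ± 0.05) and properdin (Cfp, 0.56 ± 0.06). The adjusted p = 1.28e-09 became an adjusted p = 0.125 with an estimated correlation.

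Endothelial markers rose in 14 of 23 cases and fell in 0 (19 and 0 adjusted over the list alone), with a median of 0.22 and an adjusted p = 1.73e-07, or adjusted p = 0.125 with an estimated correlation. Next to Cldn5 the lymphatic hyaluronan receptor Lyve1 (0.65 ± 0.09, its other probe at 0.14), Cd34 (0.68 ± 0.13) and Egfl7 (0.54 ± 0.10) were higher. Of 30 fibroblast and extracellular matrix genes 18 rose and 0 fell (18 and 2 adjusted over the list alone), with a median of 0.20 and an adjusted p = 5.16e-08, or adjusted p = 0.125 with an estimated correlation. Their leading members were the collagen gene Col14a1 (0.84 ± 0.05), Serpinf1 (0.76 ± 0.05), gelsolin (Gsn, 0.50 ± 0.02) and matrix Gla protein (Mgp, 0.48 ± 0.03). Smooth muscle genes rose in 17 of 27 cases and fell in 0 (19 and 1 adjusted over the list alone), among them Csrp1, Tagln (0.36 ± 0.03), the myosin phosphatase inhibitor Ppp1r14a (0.39 ± 0.07) and the mural cell gene Rgs5 (0.45 ± 0.11). Their median was 0.19 with an adjusted p = 7.64e-08, or adjusted p = 0.188 with an estimated correlation. Adipocyte genes rose in 8 of 18 cases and fell in 2 (10 and 3 adjusted over the list alone), with a median of 0.15. Cfd, the fatty acid carrier Fabp4 (0.77 ± 0.08), lipoprotein lipase (Lpl, 0.53 ± 0.14) and adiponectin (Adipoq, 0.58 ± 0.18) led this list, whose adjusted p = 0.0288 became an adjusted p = 0.272 with an estimated correlation.

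Enteric neuron and glia markers, which share the gut wall with these cells, did not pass as a group. Of 20 tested, 3 rose and 4 fell (3 and 7 adjusted over the list alone), the median was -0.07, and the camera test gave an adjusted p = 0.126, while fry called the list (adjusted p = 0.00568). Blood and erythroid markers had 0 of 7 past limma's threshold in either direction (0 and 0 adjusted over the list alone; median -0.08, adjusted p = 0.267 in camera and 0.0661 in fry). Pancreatic acinar genes, a check for neighbouring tissue, rose in 1 of 8 cases and fell in 0 (1 and 0 adjusted over the list alone; adjusted p = 0.434 in camera and 0.0485 in fry). Of 7 squamous and anal epithelium genes 0 rose and 2 fell (0 and 2 adjusted over the list alone; adjusted p = 0.993 in camera and 0.832 in fry).

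Goblet cell genes were lower, led by the main colonic mucin Muc2 (-0.61 ± 0.04, the weakest of its 3 probes at -0.27), the mucus component Fcgbp (-0.58 ± 0.05), Rep15 and Clca1 (-0.34 ± 0.06, saturated on 1 array). Of 24 tested, 2 rose and 7 fell (2 and 11 adjusted over the list alone), with a median of -0.12 and an adjusted p = 0.00353, or adjusted p = 0.445 with an estimated correlation. Surface colonocyte genes rose in 3 of 26 cases and fell in 11 (3 and 13 adjusted over the list alone). The membrane mucin Muc3 (-0.60 ± 0.10), Clca4a (-0.47 ± 0.09), the keratin Krt20 (-0.37 ± 0.02) and the microvillus protein villin (Vil1, -0.33 ± 0.06) fell, the list median was -0.10, and the adjusted p = 0.0079 became an adjusted p = 0.330 with an estimated correlation.

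Ion and water transport genes rose in 1 of 32 cases and fell in 15 (1 and 19 adjusted over the list alone), with a median of -0.14 and an adjusted p = 9.56e-05, or adjusted p = 0.132 with an estimated correlation. Besides Sgk1, the sodium pump subunit Atp1b1 (-0.41 ± 0.04), the epithelial sodium channel subunit Scnn1a (-0.39 ± 0.09) and the chloride channel Ano1 (-0.33 ± 0.07) fell. Genes typical of the distal colon segment rose in 0 of 12 cases and fell in 6 (1 and 6 adjusted over the list alone), among them Scnn1a, the peptide hormone gene Pyy (-0.27 ± 0.06), Scnn1g (-0.26 ± 0.07) and Fxyd4 (-0.23 ± 0.10). Their median was -0.13 with an adjusted p = 0.0228, or adjusted p = 0.272 with an estimated correlation. Tight and adherens junction genes rose in 3 of 26 cases and fell in 8 (3 and 11 adjusted over the list alone), with a median of -0.12 and an adjusted p = 0.0228, or adjusted p = 0.445 with an estimated correlation. The endothelial member Cldn5 was higher, while the epithelial claudin Cldn4 (-0.56 ± 0.13), the catenin Ctnna1 (-0.28 ± 0.01) and E-cadherin (Cdh1, -0.27 ± 0.05) were lower. A further probe of Ctnna1 had the opposite sign, at 0.31, and its mean over both probes was 0.01 (adjusted p = 0.841 in limma).

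**Figure D2:**
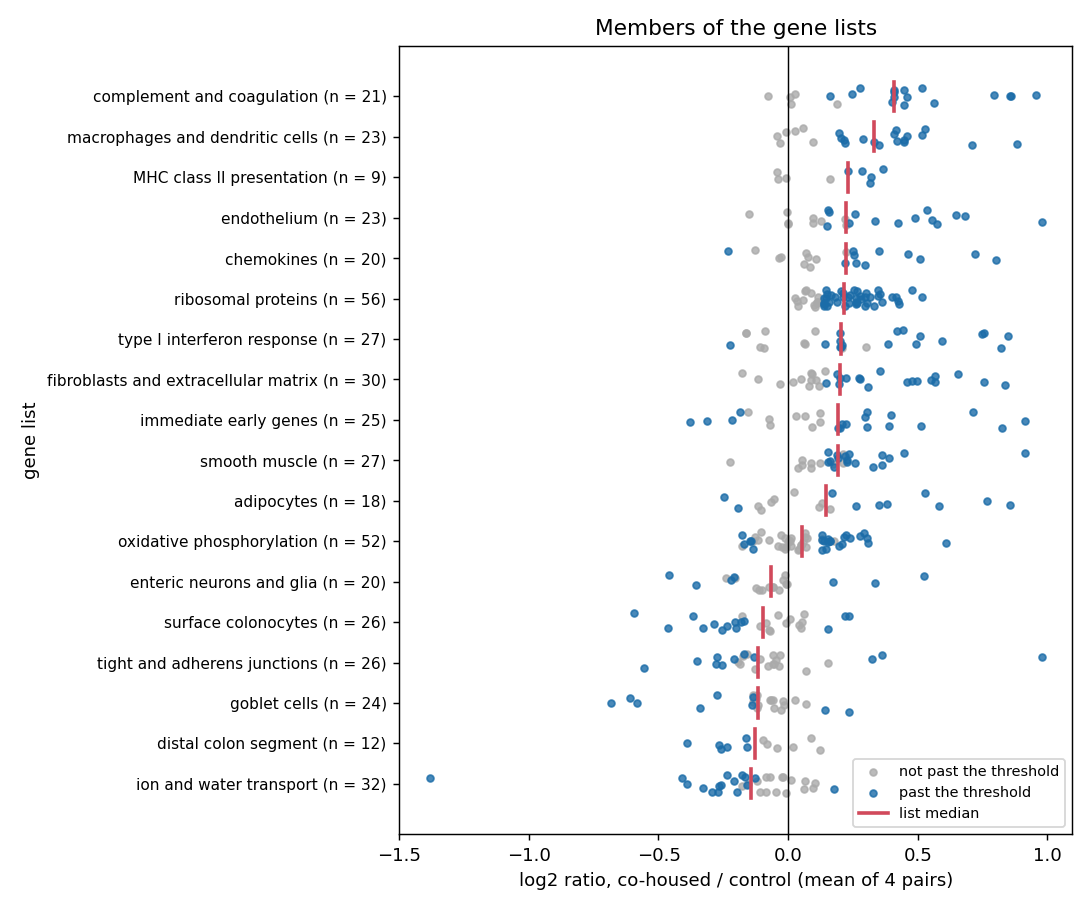
Log2 ratios (co-housed over control, mean of 4 pairs, horizontal axis) of the tested members of the 17 lists that passed the camera test and of the enteric neuron and glia list, 1 point per gene, blue where the gene passed the threshold and grey where it did not, with a red bar at the list median. Medians run from 0.41 for complement and coagulation to -0.14 for ion and water transport, and the neuron and glia median lies at -0.07.

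Other epithelial lists did not pass in the main setting. Crypt stem and progenitor genes rose in 1 of 19 cases and fell in 6 (2 and 6 adjusted over the list alone; adjusted p = 0.212). Mucin glycosylation enzymes rose in 1 of 29 and fell in 8 (1 and 9 adjusted over the list alone; adjusted p = 0.0665). Enteroendocrine genes rose in 2 of 15 cases and fell in 5 (2 and 6 adjusted over the list alone; adjusted p = 0.267). Tuft cell genes rose in 3 of 10 cases and fell in 0 (5 and 0 adjusted over the list alone; adjusted p = 0.0665). Paneth and small intestinal genes rose in 2 of 12 cases and fell in 0 (2 and 0 adjusted over the list alone; adjusted p = 0.993).

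Genes of the type I interferon response were higher. Of 27 tested, 16 rose and 1 fell (18 and 3 adjusted over the list alone), led by the ubiquitin-like modifier Isg15 (0.76 ± 0.04), Ifi27l2a (0.59 ± 0.02, its other probe at 1.22), Ifit3 (0.75 ± 0.10) and Rtp4 (0.82 ± 0.14). The median was 0.20 and the adjusted p = 9.18e-06 became an adjusted p = 0.125 with an estimated correlation. Chemokine genes rose in 10 of 20 cases and fell in 1 (11 and 1 adjusted over the list alone), among them the platelet factor gene Pf4 (0.80 ± 0.07), Ccl9 (0.72 ± 0.07), the eosinophil attractant Ccl24 (0.46 ± 0.05) and Ccl8 (0.35 ± 0.04). Their median was 0.22 with an adjusted p = 0.000328, or adjusted p = 0.241 with an estimated correlation. Genes of antigen presentation by MHC class II rose in 5 of 9 cases and fell in 0 (6 and 0 adjusted over the list alone), namely H2-Ab1 (0.32 ± 0.07), H2-Eb1 (0.31 ± 0.08), H2-DMb1 (0.37 ± 0.13), the invariant chain Cd74 (0.23 ± 0.09) and 1 more. The list median was 0.23 with an adjusted p = 0.0228, or adjusted p = 0.272 with an estimated correlation. Immediate early genes, which follow acute stimulation of cells, rose in 13 of 25 cases and fell in 4 (14 and 5 adjusted over the list alone). Egr1, Ccn1 (0.83 ± 0.15), Junb (0.51 ± 0.06) and the nuclear receptor Nr4a1 (0.71 ± 0.15) led them, the median was 0.19, and the adjusted p = 0.00586 became an adjusted p = 0.330 with an estimated correlation.

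Antimicrobial and epithelial defence genes moved both ways and did not pass as a group. Of 17 tested, 5 rose and 2 fell (5 and 3 adjusted over the list alone; adjusted p = 0.267). The lysozyme genes Lyz1 (0.78 ± 0.04) and Lyz2, near-identical copies that probes may not tell apart, were higher, and the mucosal scavenger protein Dmbt1 (-0.44 ± 0.03) and Sprr2a1 (-0.21 ± 0.03) were lower. NOD and Toll-like receptor signalling genes rose in 3 of 26 cases and fell in 2 (1 and 1 adjusted over the list alone; adjusted p = 0.974), the called members being Tab2 (-0.31 ± 0.13, its other probe at -0.16), Tab1 (-0.13 ± 0.02), Casp4 (0.22 ± 0.09), Ly96 (0.21 ± 0.14) and 1 more. In the Th17 and IL-22 axis 2 of 9 rose and 2 fell (2 and 2 adjusted over the list alone; adjusted p = 0.993). There Stat3 (-0.27 ± 0.05) and Fut2 (-0.23 ± 0.07) were lower and Socs3 (0.32 ± 0.11) and Ccl20 were higher. Ccl20 was not detected on any array in control RNA, which leaves a bound of at least 1.14-fold (adjusted p = 0.00868 in limma). A further 16 genes and transcripts called in limma were not detected in one of the RNAs, with Mup1, a urinary protein gene chosen after its value was seen, at least 1.59-fold higher.

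Interferon gamma response genes rose in 8 of 23 cases and fell in 3 (9 and 3 adjusted over the list alone; adjusted p = 0.212). MHC class I presentation genes rose in 4 of 18 and fell in 1 (5 and 3 adjusted over the list alone; adjusted p = 0.974). NF-kappaB target genes rose in 6 of 18 cases and fell in 3 (7 and 4 adjusted over the list alone; adjusted p = 0.314). Genes of the IL-4 and IL-13 response rose in 2 of 7 and fell in 3 (2 and 3 adjusted over the list alone; adjusted p = 0.434). IgA and plasma cell genes rose in 4 of 11 cases and fell in 1 (5 and 1 adjusted over the list alone; adjusted p = 0.0849), with the joining chain gene Jchain (0.46 ± 0.07), Fkbp11 (0.23 ± 0.07) and Sec11c (0.22 ± 0.08) higher and the syndecan gene Sdc1 (-0.18 ± 0.05) lower. T cell genes rose in 1 of 6 cases and fell in 1 (1 and 1 adjusted over the list alone; adjusted p = 0.779).

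Lists with fewer than 5 tested genes were not tested as groups. Of 25 inflammatory cytokine genes on the array 3 were detected often enough: the alarmin Il33 rose (0.33 ± 0.06), and Ltb (-0.04 ± 0.18) and Il18 (-0.01 ± 0.02) did not pass. Among 4 tested B cell genes Cd79b fell (-0.23), among 3 neutrophil genes Ncf4 rose (0.24), among 4 mast cell and eosinophil genes Rnase2a rose (0.29), and among 4 genes of NK and innate lymphoid cells Areg (0.37) and Id2 (0.30) rose. Of 4 sex-linked genes Kdm5c fell (-0.23, its other probe at -0.07), and Xist (-0.03) did not pass.

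Ribosomal protein genes rose almost as a block. Of 56 tested, 43 rose and 0 fell (49 and 0 adjusted over the list alone), with a median of 0.22 and an adjusted p = 1.77e-17, or adjusted p = 0.125 with an estimated correlation. The leading members were Rps24 (0.52 ± 0.01), Rps21 (0.43 ± 0.02), Rps12 (0.48 ± 0.06) and Rps25 (0.42 ± 0.03), the other Rps12 probe stood at 0.20, and 1 of the 3 Rps24 probes had the opposite sign, at -0.01. Oxidative phosphorylation genes rose in 19 of 52 cases and fell in 5 (20 and 8 adjusted over the list alone), with a median of 0.05 and an adjusted p = 0.0288, or adjusted p = 0.247 with an estimated correlation. The ATP synthase subunit Atp5e (0.61 ± 0.07) and the complex I subunits Ndufa4 (0.31 ± 0.05), Ndufb2 (0.28 ± 0.02, its other probe at 0.05) and Ndufs4 (0.29 ± 0.05) led them, and the list median turned to -0.02 when arrays were centred on their median in place of loess.

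Ratios fell with gene length across genes, and these 2 lists hold short genes. Spearman's rho between log2 ratio and genomic span was -0.21 over 11762 genes (-0.18 to -0.16 in single pairs), where genes are not independent replicates. In the shortest decile of genes 285 were higher and 83 lower, and in the longest decile 116 were higher and 271 lower. The median span was 3.2 kb for the ribosomal and 7.39 kb for the oxidative phosphorylation list, against 37.1 kb for the fibroblast and 27.1 kb for the smooth muscle list. The immediate early (3.35 kb) and chemokine (3.97 kb) lists hold short genes too. With the trend removed, the immediate early median went from 0.19 to 0.13 (adjusted p = 0.0393 in camera). That of the chemokines went from 0.22 to 0.18 (adjusted p = 0.00272 in camera).

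**Figure D3:**
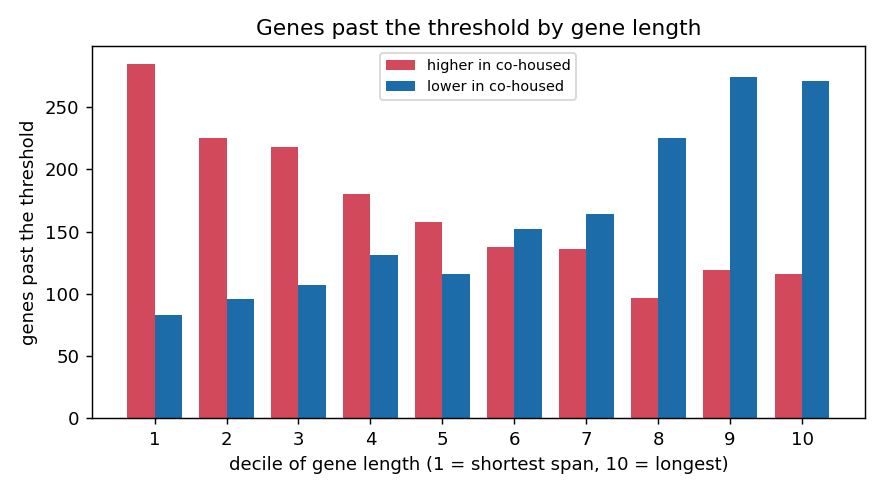
Number of genes past the threshold (vertical axis) that were higher or lower in co-housed mice, by decile of genomic span (horizontal axis, 1 the shortest). The higher genes go from 285 in the shortest decile to 116 in the longest, and the lower genes from 83 to 271.

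Among stress and regulatory lists, glucocorticoid response genes rose in 4 of 22 cases and fell in 8 (4 and 8 adjusted over the list alone; adjusted p = 0.314). Hypoxia response genes rose in 6 of 25 and fell in 7 (7 and 8 adjusted over the list alone; adjusted p = 0.471). The cell cycle list had 6 of 37 genes higher and 11 lower (7 and 13 adjusted over the list alone; adjusted p = 0.267). Circadian clock genes rose in 6 of 17 cases and fell in 4 (6 and 6 adjusted over the list alone; adjusted p = 0.84). Heat shock genes rose in 5 of 22 cases and fell in 3 (5 and 3 adjusted over the list alone; adjusted p = 0.993). Genes of the unfolded protein response rose in 3 of 29 and fell in 3 (3 and 3 adjusted over the list alone; adjusted p = 0.993). Apoptosis genes and p53 targets rose in 7 of 26 and fell in 3 (8 and 6 adjusted over the list alone; adjusted p = 0.993). Wnt targets and colon tumour genes rose in 3 of 18 cases and fell in 5 (4 and 5 adjusted over the list alone; adjusted p = 0.993).

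Apart from oxidative phosphorylation, metabolic lists did not pass either. Glycolysis genes rose in 3 of 22 cases and fell in 5 (3 and 5 adjusted over the list alone; adjusted p = 0.16). Amino acid and sugar transporters rose in 1 of 16 and fell in 6 (1 and 6 adjusted over the list alone; adjusted p = 0.142). PPAR targets and fatty acid oxidation genes rose in 3 of 33 and fell in 8 (3 and 8 adjusted over the list alone; adjusted p = 0.574). Fatty acid synthesis genes rose in 3 of 20 cases and fell in 6 (4 and 6 adjusted over the list alone; adjusted p = 0.267). Cholesterol biosynthesis genes rose in 2 of 25 and fell in 5 (5 and 5 adjusted over the list alone; adjusted p = 0.993). Bile acid genes rose in 2 of 11 and fell in 2 (3 and 2 adjusted over the list alone; adjusted p = 0.945). Xenobiotic and retinol metabolism genes rose in 9 of 43 cases and fell in 10 (10 and 10 adjusted over the list alone; adjusted p = 0.993).

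In all, 17 of the 50 tested lists passed camera, 12 higher and 5 lower. Lists share members, so these calls are not all independent. Another list also held 15 of 32 ion and water transport, 11 of 26 surface colonocyte, 6 of 12 distal colon and 7 of 24 goblet cell genes. For the ribosomal and type I interferon lists this number was 0. With an estimated correlation camera called 0 lists, although 10 had an unadjusted p under 0.05, and fry called 35. The estimate lay below the preset 0.01 for fibroblast (-0.014), type I interferon (-0.034), ion and water transport (-0.021) and oxidative phosphorylation (-0.015) genes, among others. For other lists that had passed it lay above, up to 0.172 for goblet cells. Where it lay below, a larger correlation between genes cannot be why the call ended, and the cause was not tested. On slide 1 alone 16 lists passed and on slide 2 alone 15. The median, mean and test of 13 lists, none of them among the 17, differed in sign. These were the MHC class I, NOD and Toll-like receptor, unfolded protein, heat shock, circadian, PPAR, cholesterol, xenobiotic, bile acid, Wnt, apoptosis, Paneth and squamous lists. Further settings ended the call of the junction list (adjusted p from 0.0544 without pair 4 to 0.318 on the Cy3 arrays alone) and of the oxidative phosphorylation list (0.0515 on slide 1 alone to 0.586 on the Cy3 arrays alone).

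The gene missing in the cage mates, Nod2, could not be followed in these wild-type mice, since its single probe was not detected on any array. Nnt, a mitochondrial transhydrogenase gene partly deleted in C57BL/6J, stood at 0.06 ± 0.06 and did not pass (adjusted p = 0.331 in limma). The other 2 detected Nnt probes had the opposite sign.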

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

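The counts over other splits of the samples were planned, while the tests of tissue makeup, gene length, probe intensity and repeated RNAs below were chosen only after the results they bear on had been seen.

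Among the 100 named genes with values, 8 had 1 pair far from its other pairs. Pair 3 stood apart for Clec10a at 0.78 (others 0.91 to 0.93), Sgk1 at -1.56 (-1.33 to -1.32), Plec at -0.25 (-0.83 to -0.77) and C1qa at 0.46 (0.39 to 0.40). Pair 2 did so for Socs3 at 0.49 (0.26 to 0.27) and Rps24 at 0.51 (0.52 to 0.52), pair 1 for Muc2 at -0.67 (-0.60 to -0.58) and pair 4 for Rgs5 at 0.28 (0.49 to 0.52). Chance gives such a value in about 1 in 20 groups of 4.

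Control spots outside the comparison carried large ratios. Of 10 spike-in control probes, present in 32 spots each, 9 had 1 sign on all 8 arrays, and their mean log2 ratios reached 3.10 and -2.57. If each RNA kept its own spike-in mix across the dye swap, the arrays are oriented alike. Which RNA carried which mix is not given in the sources used here.

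As for chance, 1 of the 8 choices of sign for the 4 pair ratios gave as many genes as the 3485 observed, namely the real one. The highest other choice gave 0 in limma (634 genes at an unadjusted p under 0.05, against 5150), and 8 choices are too few for a share under 0.05. When the 8 RNAs were split 4 against 4 without pairing, 1 of 35 splits, the real one with 2025 genes, gave as many, and the highest other gave 4. That share would count against chance only if the 8 RNAs were independent. RNAs that shared arrays were correlated, so chance is not excluded. If the pairs repeat one comparison, these counts say nothing about chance differences between mice. The split with 4 genes was slide 1 against slide 2. At an unadjusted p under 0.05 in limma, the highest other of the 35 splits gave 1803 genes, against 3791 for the real one. Of the 8 splits that part all 4 pairs, the highest besides the real one gave 0 genes in limma (624 at an unadjusted p under 0.05, against 3791).

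Markers of several non-epithelial cell types were higher and epithelial genes lower, which could come from a piece of tissue with less epithelium in the co-housed samples. If a lower share of epithelium raised every other cell type alike, neuron and glia markers would be higher too. The median of these 20 markers lay -0.28 on the log2 scale from that of 121 other non-epithelial markers (-0.07 against 0.21, permutation p = 0.00034, 100000 permutations). Those 121 came only from lists that had passed as higher, and the neuron list was already known not to have passed. That choice largely set the difference, so it cannot argue against a lower share of epithelium, which stays open. Left out were T cell (median 0.03), plasma cell (0.17) and erythroid markers (-0.08). Members of the neuron list lay on both sides, Vip at 0.52, S100b at 0.34 and Nos1 at -0.46, and 1 of its 20 genes was also held by another list. With the trend with genomic span removed, 10 of the 10 lists of this pattern still passed camera at the preset correlation. This argues against that trend as the whole cause. Span is not transcript length, so a bias with transcript length stays open. A different depth of sampling that takes vessels and muscle but not nerve cells, more macrophages or stroma, and a response to the co-housing all stay open and untested.

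Ribosomal protein genes were higher, and short genes in general were higher, so that RNA quality or labelling that favours short transcripts may have contributed. With the length trend removed the ribosomal list kept a median of 0.16 (0.22 before) and an adjusted p = 5.9e-12, and its median lay above 100% of 10000 random lists matched on probe intensity, the highest of which reached 0.14. The trend with genomic span was therefore not the whole cause, and the median went beyond these intensity-matched lists. The matched lists drew unrelated genes, so their spread understates that of genes that move together. With an estimated correlation the list did not pass camera (adjusted p = 0.125). Span is not transcript length, so RNA quality or labelling that favours short transcripts stays open. For oxidative phosphorylation the same correction ended the call (adjusted p = 0.281), the mean going from 0.07 to 0.03 with an SD over genes of 0.16 before and 0.15 after, because the shift fell while the spread stayed. For that list length bias and a real difference cannot be told apart, and the co-housing stays open for both.

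The 4 pairs differed from one another no more than the dye-swapped arrays of one pair, with 5.05% of genes at p under 0.05. That is what 4 hybridisations of the same RNAs, or of pools, could give, while a between-sample SD of 0.1 gave 16.8% in simulated data. Titles number all 4 co-housed RNAs as replicate 1, but they number the control RNAs 1 to 4, and the descriptions and array names give 4 distinct numbers for both, which goes against repeated use of the same RNAs. The labels' design text gives 4 biological replicates, which goes against it too. Very similar mice would give the same share, so repeated RNA, pools and alike animals cannot be told apart from the array values alone.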

How the results depend on the processing

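The scanner's own background-subtracted medians, leaving out array 6 and removing the gene length trend were chosen after seeing the data, and all other alternatives were planned. The 3485 genes became 1989 with no filter on dim probes (1087 higher, 902 lower; 26621 genes and transcripts tested), 1971 on the arrays with the co-housed RNA in Cy3 (885 and 1086) and 2025 with no replicate block, that is without the pairing (1111 and 914). It was 883 on slide 1 alone (541 and 342), 636 on slide 2 alone (367 and 269) and 2062 with the scanner's medians (1052 and 1010). Fewer pairs or more tests lower the count by construction for the filter, the slides and the left-out pairs, and for the Cy3 arrays, the pairing and the scanner's medians the cause was not tested. Leaving out 1 pair gave 1934 to 3040 genes (1047 to 1631 higher, 887 to 1409 lower), the lowest without pair 2. With median centring in place of loess 4339 genes passed, 1119 higher and 3220 lower, so 25.8% of the calls were higher against 51.6%. The median of all genes moved to -0.06, and the split between higher and lower is relative to the loess fit.

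Other settings stayed within 1.5 times: 3071 without background correction, 3668 with the strict filter, 3491 with the mean of a gene's probes, 4008 with a dye effect over 8 arrays, 3871 on the Cy5 arrays, 3063 with the slide as a block, 4131 with a trended robust prior, 3914 with array weights, 2871 from the deposited table, 3055 without array 6, 3266 with the length trend removed, 4735 at a threshold of 0.10 and 3977 over all probes. Quantile scaling of intensities between arrays moves no ratio by construction. In the other settings the share of the 3485 calls that were also called with the same sign ran from 17.8% on slide 2 alone to 99.0% with array weights. It was 65.6% on the Cy5 arrays alone and 42.1% on the Cy3 arrays alone. The planned processed signals were not run.

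Of the 50 lists, 17 passed in the main setting, 0 in camera with an estimated correlation, 35 in fry and 15 to 19 in every other setting. The junction list also lost its call in 7 of the other settings, the oxidative phosphorylation list in 6, the distal colon and adipocyte lists in 2 each, and the surface colonocyte, MHC class II and immediate early gene lists in 1 each. Some lists that did not pass in the main setting did so in others. Of 25 settings, fry included, tuft cells passed in 9, mucin glycosylation in 5, and IgA and plasma cells and glycolysis in 4 each. The fit without the pairing changed no call of the 17 lists and 5 of those of the named genes. The 1 result that reversed was Ctnna1, at 0.014 (adjusted p = 0.841) with the mean of its probes against -0.28, because its 2 probes differ in sign. The named genes most open to the setting were Ly96 and Tab1, each of which missed the threshold in 13 of 23 settings. Over the settings, Ccn1 ran from 0.75 to 1.77, Isg15 from 0.69 to 1.41 and Inmt from 1.20 to 1.57. The order of the highest ratios therefore depends on the setting. Between 37.7% and 46.1% of spots per array were not found, so genes expressed at a low level, most cytokines among them, are beyond what these arrays resolve.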

Other observations

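The mitosis and replication parts of the cell cycle list and the tests on them were chosen only after their values had been seen, as were the genes named here outside the lists.

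Within the cell cycle list, which did not pass as a whole (adjusted p = 0.267), the called members divided by function. Of 22 mitosis genes 11 were lower and 0 higher, with a mean of -0.18 (SD 0.16 over genes). They include the proliferation marker Mki67 (-0.53 ± 0.08), the kinetochore protein gene Cenpf (-0.50 ± 0.10) and Plk1 (-0.30 ± 0.10). Of 15 DNA replication genes 6 were higher and 0 lower, with a mean of 0.13 (SD 0.13), among them the ubiquitin ligase gene Uhrf1 (0.33 ± 0.11), Mcm6 (0.26 ± 0.08) and the sliding clamp gene Pcna (0.21 ± 0.03). The other 11 mitosis and 9 replication genes did not pass. The means lay -0.31 apart, and -0.308 with the trend with genomic span removed. This argues against that trend as the whole cause and leaves a bias with transcript length open. Since the parts were formed after the values were seen, the difference cannot be tested on these data.

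Several responders to corticosteroids and low oxygen were lower beside Sgk1, Ankrd37 and Ddit4, among them the metallothionein genes Mt2 (-0.47 ± 0.06) and Mt1 (-0.21 ± 0.01) and the steroid-inactivating enzyme gene Hsd11b2 (-0.31 ± 0.07). Others of the same lists were higher, among them Bnip3 (0.46 ± 0.07), Pfkfb3 (0.39 ± 0.08) and Cdkn1a (0.26 ± 0.01), and neither list passed. Circadian clock genes also moved both ways, with Nr1d2 (0.52 ± 0.06), Hlf (0.49 ± 0.09) and Dbp (0.35 ± 0.04) higher and Bhlhe40 (-0.44 ± 0.05), Ciart (-0.23 ± 0.10) and Per2 (-0.19 ± 0.11) lower. The hour at which tissue was taken is not given in the sources used here.

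Further genes at least 1.5-fold higher included the calcium-binding protein gene S100a4 (0.75 ± 0.04), the collagen-processing enhancer Pcolce2 (0.83 ± 0.15) and the interferon-induced gene Oasl2 (0.85 ± 0.22). Among those at least 1.5-fold lower were the DNA methyltransferase gene Dnmt3a (-0.66 ± 0.26), the planar polarity cadherin Celsr1 (-0.65 ± 0.11) and the histone methyltransferase gene Kmt2c (-0.63 ± 0.13, the weakest of its 3 probes at -0.18).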
